A study of Mus musculus with 13 samples.

How the data were processed

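The series held 13 two-colour hybridisations of mouse total RNA, each with an RNA source named NT1 in one dye and a source named TBV in the other. Per the labels, NT1 was in Cy5 on 7 arrays and TBV was in Cy5 on 6. The arrays fell into 4 source pairs: NT1p14 with TBVp13 on 5 arrays, NT1p12 with TBVp12 on 4, NT1 1 with TBV2 on 2, and NT1p12 with TBVp13 on 2. The number after p was read as the passage, since the labels speak of different passages.

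The deposited table held 1 value per probe and array for 20205 probes, and 437 of these probes had no value on any array. The values were treated as log2 ratios of the channels as deposited by the authors. Neither the log base, nor the numerator, nor the normalisation within the arrays is given in the sources used here. The values were signed, array medians lay at 0 or -0.0025, and the largest size was 15, which is below the log2 of a 16-bit scanner range (16) and above its natural log (11.1). The ratio was read as Cy5 over Cy3 and turned to NT1 over TBV, which matches the mean correlation below 0 between opposite dye orientations in the 3 independent pairs (-0.17, -0.11 and -0.02), although it was 0.08 in NT1p12 with TBVp13. This check cannot tell Cy5 over Cy3 from the reverse for the whole table, so the direction of all signs together stays unsettled.

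Part of the decimals were missing from the deposited values, and when they were lost is not known here. Of all 220028 values, 19.3% were whole numbers, and of the 19859 values of size 1 or more only 79 had decimals. In a fixed column order that follows the source pairs, 34152 values came after the first whole number of their row and 54 of them had decimals. A 0 on such an array therefore stands for a range of small ratios, and 11941 rows held no whole number.

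Each array was centred on its median. For each source pair the mean of the arrays with TBV in Cy5 was subtracted from the mean of those with NT1 in Cy5 and the difference was divided by 2, so that a dye effect cancels. Arrays of the same RNA sources are technical repeats and counted as 1 replicate. NT1p12 with TBVp13 shares both sources with other pairs and served as a check only, which left n = 3. Probes with a value in all 3 pairs (15973) were tested against 0, two-sided, with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same fit on the sum of both orientations measured the dye effect. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

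For gene lists, probes of a gene were averaged (7968 genes), and 22 lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Lists with fewer than 3 measured genes were left out, which left 20. The list of Xist and Y-linked genes had no measured member and the Sall family had only Sall4.

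Probes were named through the platform annotation: 11723 had 1 gene symbol, 806 had several and stayed unnamed, and 7676 had none. Of the symbols, 11590 were matched by Entrez ID to the current RefSeq gene table and 0 were updated.

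The rule for named genes, also fixed before the data were examined, was the Sall family, Pou5f1, Nanog, Sox2 and Cdx2 whatever their values, and genes past the threshold with the same sign in all pairs. As fewer than 10 probes passed, the rule gave the 10 genes with the smallest p in each direction. Examples from gene lists beyond these were chosen after their values were seen.

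On simulated pairs with the measured spread, the fit called 13% of changes of 1 on the log2 scale and 76% of changes of 2. The simulated pairs were independent and not rounded, and array noise was added to a spread that already holds it. In the data, NT1p14 with TBVp13 and NT1p12 with TBVp12 correlated at -0.50, so these shares need not hold here. The number of arrays and of independent pairs limits the precision, and the table carries no intensities. The p-values measure the spread among preparations of 1 NT1 and 1 TBV line as far as the labels tell, not among independent clones. Alternatives covered the replicate unit, dye orientation, centring, scaling, missing values, variance moderation, thresholds and leaving out pairs or arrays.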

Results

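Gene expression was compared between 2 kinds of mouse RNA source, NT1 and TBV, on 13 two-colour arrays. The series title sets a homozygous Sall4 mutation beside NT1. Sall4 encodes a zinc finger transcription factor of pluripotent cells. TBV2 is also the name of a mouse embryonic stem cell line, but the labels do not state a cell type. Of 4 pairs of RNA sources, 3 were independent of each other: NT1p14 with TBVp13, NT1p12 with TBVp12, and NT1 1 with TBV2. Probes with a value numbered from 14314 to 18381 per array.

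The first comparison asked how NT1 differed from TBV. The Sall4 probe gave a log2 ratio of NT1 over TBV of -0.28 ± 0.33 (SD, n = 3). Its pair values were 0.07 in NT1p14 with TBVp13, -0.59 in NT1p12 with TBVp12 and -0.32 in NT1 1 with TBV2, and 10 of the 13 arrays lay below 0. The difference did not exceed the spread between pairs (limma, adjusted p = 1.00). Whether this probe lies in the part of the gene that was deleted is not known here, so it does not check the labels. All signs rest on reading the values as Cy5 over Cy3, which the sources used here do not settle.

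Pou5f1, which encodes the pluripotency factor Oct4, had a log2 ratio of -0.59 ± 0.38 (SD, n = 3), with -0.25, -1 and -0.51 in the 3 pairs. Of its 13 array values 8 were below 0 and 5 were exactly 0. Nanog, Sox2, Cdx2, Sall1, Sall2 and Sall3 had 0 probes named with those symbols. No probe passed the threshold in limma (0 of 15973 probes, smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 164 probes, 94 higher and 70 lower in NT1, where chance alone gives 799.

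The genes with the smallest p, none past the threshold, are given by value. On the higher side were Dnmt3l, a regulator of de novo DNA methylation, at 0.89 ± 0.35 (SD, n = 3) and Mdh1b at 1.04 ± 0.67. Mdh1b was at 1.77 in NT1p14 with TBVp13, against 0.46 in NT1p12 with TBVp12 and 0.88 in NT1 1 with TBV2. Cox5a, a subunit of cytochrome c oxidase, stood at 0.59, Slc14a2 at 0.56, and Ccdc74a and Acy3 at 0.53 each. Colgalt1 at 0.51, Cdo1 at 0.47, Afg3l1 at 0.45 and Brk1 at 0.42 completed that side. On the lower side Hnrnpl, an RNA-binding splicing regulator, was at -1.44 ± 0.59 and Rara, the retinoic acid receptor alpha, at -1.17 ± 0.50. Hcfc2 was at -1.11, Stmn2 at -0.95, Platr10 at -0.77 and Lyzl4 at -0.63 ± 0.02. Slc29a1 at -0.57, Spink1 at -0.53, Sfxn1 at -0.52 and Txnl4a at -0.46 completed the lower side. Of the 22 genes named so far, 8 moved by over 1.5 times in a single dye orientation. With NT1 in Cy5 only and TBV in Cy5 only, in this order, Acy3 was at -0.21 and 1.27, Brk1 at -0.15 and 0.98, Colgalt1 at 0.13 and 0.89, Cdo1 at 0.81 and 0.13, Platr10 at -0.20 and -1.33, Hcfc2 at -1.55 and -0.67, Txnl4a at -0.30 and -0.62, and Sfxn1 at -0.16 and -0.89. A single array moved 5 as much: Acy3 went to 0.20 and 0.86 without arrays 3 and 4 of NT1p12 with TBVp12, and Txnl4a to -0.29 without array 1 of that pair. Afg3l1 went to 0.70 and 0.20 without arrays 3 and 5 of NT1p14 with TBVp13, Brk1 to 0.62 and 0.21 without arrays 1 and 2 of NT1 1 with TBV2, and Platr10 to -0.48 without the latter array. Lyzl4 was below 0 on 13 of 13 arrays and Rara on 12 of 13, with 1 value of 0. Whole numbers made up all 13 values of Dnmt3l, all 12 of Hnrnpl and all 12 of Hcfc2. They made up 12 of 13 for Rara and for Platr10 and 11 of 13 for Stmn2, against 4 of 13 for Ccdc74a and 0 for Lyzl4. Ratios that rest mostly on whole numbers are coarse. Other probes of the same gene gave -0.21 and -0.02 for Stmn2, 0.06 for Hcfc2, 0.14 for Ccdc74a, and 0.83 and 0.25 for Txnl4a, so these genes are uncertain.

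**Figure D1:**
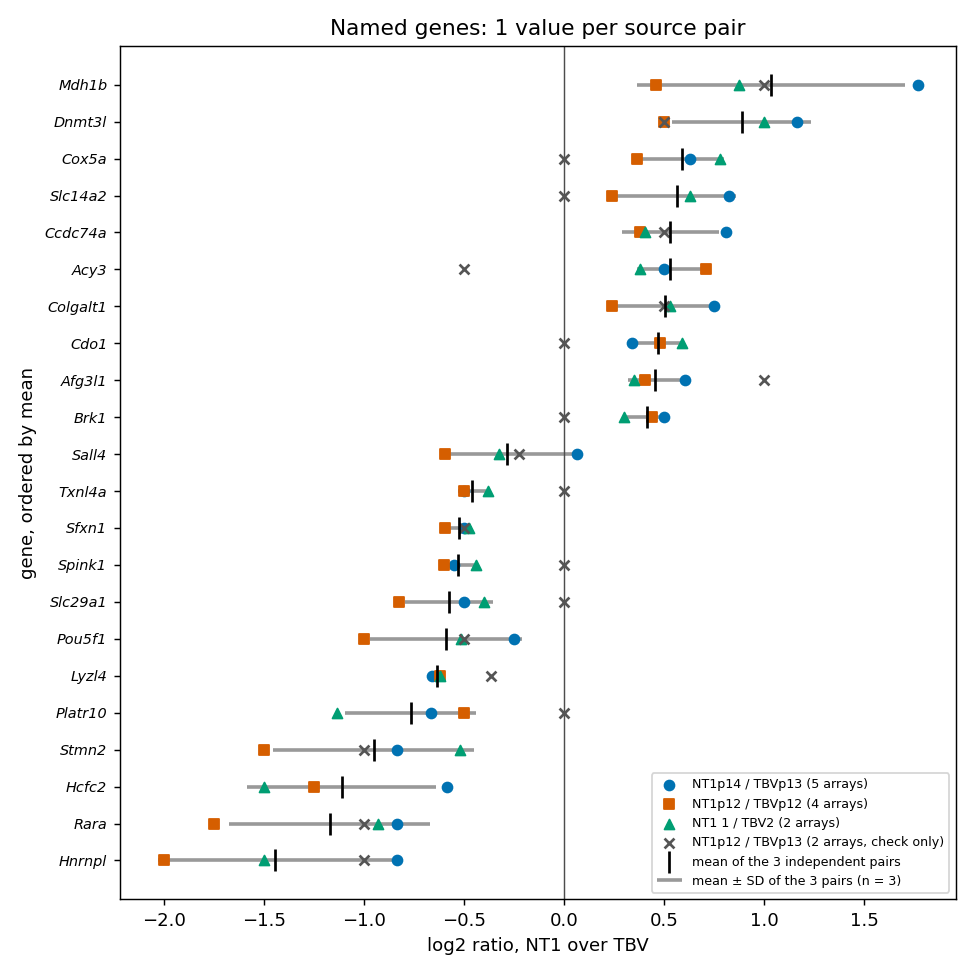
Log2 ratio of NT1 over TBV (horizontal axis) for each gene named by the rule (vertical axis), with 1 symbol per source pair, a black tick at the mean of the 3 independent pairs and a grey bar of 1 SD to each side. Pair values of Hnrnpl run from -2 to -0.83 and those of Sall4 from -0.59 to 0.07.

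With all 13 arrays, a dye term and the source pair as a random block, limma called 3 probes, all lower in NT1: Lyzl4 at -0.60, Rara at -1.15 and Sfxn1 at -0.53, with adjusted p of 0.0020, 0.0098 and 0.015, against 1.00 for each in the fit on 3 pairs. Of these, Sfxn1 depended on the dye orientation (-0.16 against -0.89). The block was fitted on Cy5 over Cy3 ratios, so it takes up a shift common to both dye orientations of a pair. It does not take up a pair's own NT1 over TBV difference, which changes sign with the orientation. The pair was therefore not the unit of replication in this fit. It counts repeats of the same RNA, and the consensus correlation within pairs was -0.16, so these p-values are too small for a statement on new preparations.

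The gene list tests asked whether groups of related genes moved together. Of 21 measured genes of pluripotency and embryonic stem cells, 7 were below 0 in all 3 pairs and 1, Dnmt3l, was above 0 in all 3. These counts hold for the pair directions as labelled. Turning a pair puts each of the 7 above 0 in that pair, so none of them can remain. With NT1p14 with TBVp13 turned, 4 others were below 0 in all 3 (Nr0b1, Lin28a, Gdf3 and Nr5a2). With NT1p12 with TBVp12 turned, 0 genes were, and with NT1 1 with TBV2 turned, 1 was (Tcl1). Besides Pou5f1 the 7 were Zfp42 at -0.78, Fgf4 at -0.48, Klf4 at -0.32, Esrrb at -0.25, Zfp296 at -0.24 and Utf1 at -0.22. In NT1 1 with TBV2, however, Zfp42 was at -0.01 and Esrrb at -0.02, about 0. Utf1 was at -0.06 in NT1p14 with TBVp13 and Zfp296 at -0.09 in NT1p12 with TBVp12. Pou5f1 was below 0 in NT1p14 with TBVp13 on array 3 alone, at -1 against 0. Without NT1p12 with TBVp12 Zfp42 was at -0.30 and Esrrb at -0.14. The list as a whole did not pass (camera, adjusted p = 0.21, and adjusted p = 0.99 with an estimated correlation), and 0 members passed, either over all genes or adjusted over the list alone. Its median was 0.14 in NT1p14 with TBVp13, -0.28 in NT1p12 with TBVp12 and -0.01 in NT1 1 with TBV2. A single pair decided the call: without NT1p14 with TBVp13 the list passed as lower (median -0.24, camera adjusted p = 0.026), and without NT1p12 with TBVp12 its median was 0.08 (camera adjusted p = 0.92).

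Of 12 measured trophectoderm and trophoblast genes, 6 had a mean above 0 and 6 below, and the list median was 0.01. In all 3 pairs 1 gene was below 0, Lgals3 (-0.03, -0.01 and -0.18). Above 0 in all 3 pairs were 3 genes: the epithelial keratins Krt18 at 0.38 and Krt19 at 0.21, and the tight junction gene Cldn4 at 0.33. The dye orientation moved 2 of them: Cldn4 was at 0.60 with NT1 in Cy5 only and at 0.06 with TBV in Cy5 only, and Krt19 at 0.40 and 0.02. Without NT1p12 with TBVp12, Krt19 was at 0.10 and Krt18 at 0.25. That list did not pass (camera, adjusted p = 0.35). The list tests on all 13 arrays, with a dye term and the source pair as a random block, used only the 5829 genes with a value on every array. There the pluripotency list (20 genes) passed as lower (camera, adjusted p = 0.021) and the trophectoderm list (10 genes) as higher (camera, adjusted p = 0.011). That call is lost when 13 arrays are taken as independent and the correlation is estimated (camera, adjusted p = 0.91 and adjusted p = 0.37), so it rests on the preset correlation. Here too the block did not take up a pair's own NT1 over TBV difference, so the pair was not the unit of replication.

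The 20 measured fibroblast genes, which would mark feeder cells, had a median of 0.44 in NT1p14 with TBVp13, -0.25 in NT1p12 with TBVp12 and -0.36 in NT1 1 with TBV2. Acta2 was at 1.17, -0.68 and -0.75 in the same order and Col1a1 at 0.88, -0.62 and -0.56. Cell cycle genes had medians of 0.45, -0.33 and 0.08, ribosomal protein genes 0.42, -0.48 and 0.10, and proteasome genes 0.38, -0.28 and 0.02. Among 16 chromatin genes Dnmt3l alone passed adjusted over the list alone (limma, adjusted p = 0.0495), and 0 passed over all genes. All 13 Dnmt3l values were whole numbers. None of the 20 lists passed with camera at either correlation or with fry. The other lists, for endoderm, mesoderm, neuroectoderm, germ cell, imprinted, interferon, stress, glycolysis, cholesterol, oxidative phosphorylation, p53 target, signalling and cytoskeleton genes, had camera adjusted p from 0.21 to 0.99.

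**Figure D2:**
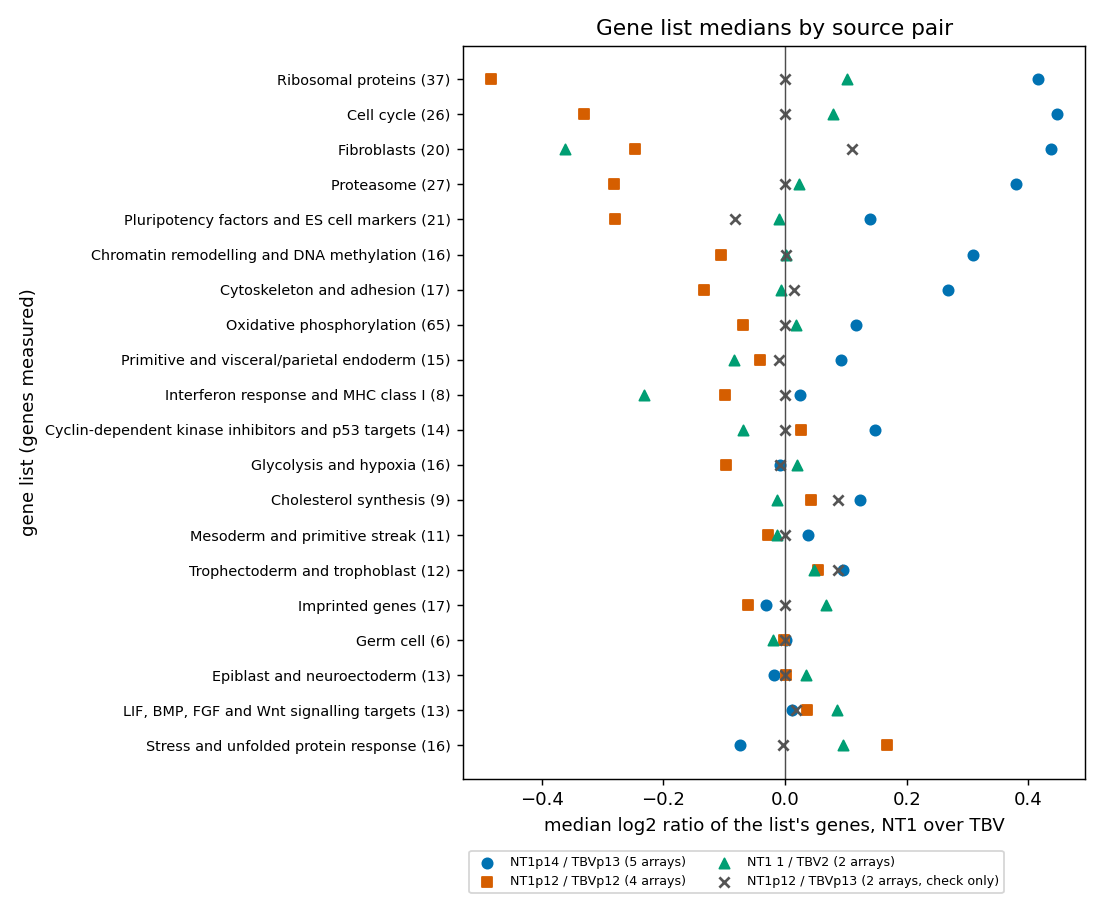
Median log2 ratio of NT1 over TBV (horizontal axis) of each gene list (vertical axis, genes measured in brackets), with 1 symbol per source pair. Ribosomal protein genes lie at 0.42 in NT1p14 with TBVp13 and at -0.48 in NT1p12 with TBVp12, the widest gap between these pairs.

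The source pairs did not give the same picture. Over all probes NT1p14 with TBVp13 and NT1p12 with TBVp12 correlated at r = -0.50 across probes (Spearman -0.59), while NT1 1 with TBV2 correlated at 0.13 with the first and at -0.04 with the second. Probes are not independent replicates. Read as NT1 over TBV, single arrays of the first and the second pair correlated below 0 in 9 of 10 combinations of opposite dye orientation (-0.55 to 0.01) and in 8 of 10 of the same orientation (-0.36 to 0.24). A dye effect common to both pairs lowers the former and raises the latter. With the signs of NT1p14 with TBVp13 turned, 0 probes passed and 1083 had an unadjusted p under 0.05. The fibroblast, proteasome, ribosomal protein and cell cycle lists then passed as lower with the preset correlation, and 0 lists with an estimated one. Pou5f1 was then at -0.42 and Sall4 at -0.33, while Mdh1b went to -0.14 and Ccdc74a to -0.01.

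**Figure D3:**
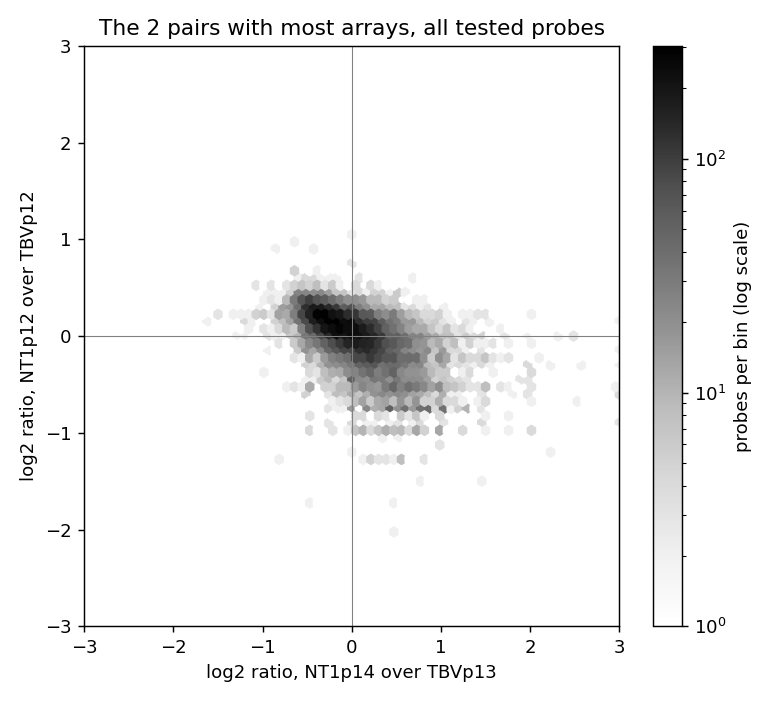
Log2 ratios of NT1p12 over TBVp12 (vertical axis) against NT1p14 over TBVp13 (horizontal axis) for 15973 probes, shaded by probes per bin on a log scale, with 53 probes beyond the axis limits. The cloud runs from upper left to lower right, at r = -0.50.

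NT1p12 with TBVp13 repeated RNA sources of the other pairs. Its Pou5f1 value was -0.50, its Rara value -1, its Dnmt3l value 0.50, its Krt18 value 0.38 and its Sall4 value -0.22. Acy3 lay on the other side there, at -0.50 against 0.53 in the 3-pair mean. Cox5a, Cdo1, Slc14a2, Brk1, Platr10, Spink1, Slc29a1 and Txnl4a were at 0 in it. On its 2 arrays 40.4% and 40.3% of the values were whole numbers, so a 0 there stands for a range of small ratios. The 0 of Brk1 was the mean of -1 and 1. Over all 14299 probes measured in it, the 4455 at exactly 0 included, it correlated with the 3-pair mean at r = 0.17. Leaving out the values of 0, its sign was that of the 3-pair mean in 54.3% of the probes. Among the 145 probes with an unadjusted p under 0.05, 72 were at 0, and of the others 82.2% had the same sign (60 against 13). Shared RNA sources alone, in a simulation of unchanged probes without array noise, gave 69.6% and 93.7%, so this share is no separate evidence.

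Passages within a line were compared through the shared sources, with 1 source each and no test. NT1 at passage 14 minus passage 12 had an SD over probes of 0.54, and TBV at passage 13 minus passage 12 one of 0.47. Each is a difference of 2 pair values, so it carries the array noise of both. The ratio of NT1 over TBV within a single pair had an SD of 0.55, 0.48, 0.26 and 0.24 in the 4 pairs. The ribosomal protein genes had a median of 0.42 in the NT1 passage difference and of -0.49 in the TBV passage difference. As the linking pair NT1p12 with TBVp13 had a ribosomal median of 0 on both arrays, these restate the pair medians of 0.42 and -0.48. The fibroblast genes had 0.08 and -0.33.

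The dye effect asked how much of a ratio in a single orientation came from the dyes. Zfp653 at -0.92 ± 0.10 (SD, n = 3) and Polr3f at -0.72 ± 0.05 were among the named genes with the smallest p, both lower in Cy5. In limma 0 probes passed (smallest adjusted p = 0.14) and 3868 had an unadjusted p under 0.05. With all 13 arrays taken as independent, the dye term passed on 320 probes. The dye component correlated between pairs at 0.27 to 0.34 across probes.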

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

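The comparison of lists between pairs and the tests of fibroblast content, of a reversed numerator and of expressed genes as a group were chosen after the values they bear on had been seen, and the test of exchanged RNA labels before.

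Among 44 groups of 4 or 5 arrays tested for an array far from the others, 5 stood out. The rule is set to flag about 1 in 20 groups of normally spread values. That rate was not measured here and need not hold for whole numbers. In NT1p14 with TBVp13, array 4 read 0 for Rara and for Stmn2 against -1 on the other arrays, and array 3 read -1 for Pou5f1 against 0. In NT1p12 with TBVp12, array 3 read 1 for Colgalt1 against -0.04 to 0, and array 2 read -1 for Rara against -2. All 5 sit on values that had lost their decimals.

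Of 20 lists, 7 differed between NT1p14 with TBVp13 and NT1p12 with TBVp12 in an exact permutation of the 9 arrays over 126 splits with Benjamini-Hochberg adjustment. These arrays are technical repeats of 1 source pair each, so the test compares the pairs and not the passages. The difference of the mean log2 ratio was 0.73 for cell cycle genes and 0.29 for oxidative phosphorylation genes (exact permutation, adjusted p = 0.045 for both). It was 0.68 for proteasome, 0.59 for fibroblast, 0.51 for pluripotency, 0.45 for cytoskeleton and 0.40 for endoderm genes (exact permutation, adjusted p = 0.032 for each). Ribosomal protein genes had the largest difference, 0.78, and did not pass (exact permutation, adjusted p = 0.060). Their medians by array were 0, 0.21, 0, 1 and 1 in NT1p14 with TBVp13, so that arrays 4 and 5, on whole numbers, carried that shift, and -0.66, -0.59, 0 and -0.64 in NT1p12 with TBVp12.

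The opposite ratios of these pairs may be technical or biological. Ratios of 1 pair deposited as Cy3 over Cy5 are argued against by the dye component, which correlated at 0.34 between the pairs. A reversed numerator needs a value below 0. The median difference of the cell cycle genes, 0.81 (SE over genes 0.13), went with the fibroblast genes, where fibroblast content alone was predicted to move them against these. A shift of expressed genes as a group would give the same sign, so the cell cycle genes cannot decide on fibroblast content. Exchanged RNA labels in 1 pair cannot be told apart from a true difference: 4 pluripotency genes (Esrrb, Zfp42, Fgf4 and Dnmt3l) had the same sign on all non-zero arrays of both pairs, which was the result set beforehand as counting against it, but 4 others had opposite signs, so exchanging the labels would give the same count (over all 7968 genes, 69 had the same and 686 opposite signs). NT1p12 with TBVp13 shares 1 source with each of these pairs. Across probes it correlated at 0.11 with NT1p14 with TBVp13 and at 0.01 with NT1p12 with TBVp12. Both values are near 0, so it does not tell which pair, if either, was reversed. A shift of strongly expressed genes as a group goes with the median difference of 1.08 for ribosomal protein genes. It was 0.14 or less for germ cell, mesoderm and neuroectoderm genes. Oxidative phosphorylation genes, however, reached only 0.20 (2.0 SE), the ribosomal shift was uneven between arrays, and the table holds no intensities. Each SE here was taken over the genes of a list as if independent. The correlation between genes was estimated at 0.53 for the cell cycle and 0.36 for the ribosomal list, so such SEs are too small. The passages named in the labels stay open as an untested biological explanation.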

How the results depend on the processing

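The settings with turned signs, with ribosomal centring, with probes that kept their decimals, with covariates, named genes without single arrays, and the list tests on arrays taken as independent were added after the data were seen. The count of 0 probes past the threshold held in all settings on source pairs, including each pair and each array left out, except centring on ribosomal protein genes, with 1 unnamed probe. On 13 arrays it was 3 with the pair as a random block, which did not make the pair the unit of replication, and 10 as independent arrays. It was 98 with a ribosomal and 140 with a proteasome covariate, both fitted because 0 had passed and both counting technical repeats, so neither replaces the count of 0. The cause was not tested.

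The 164 probes at an unadjusted p under 0.05 became 319 with 4 pairs, 531 with NT1 in Cy5 only and 1112 with TBV in Cy5 only. They became 286 with scaled arrays and 91 after averaging per gene (fewer tested). With signs not turned the fit was that of the dye effect, with its 3868 probes, and no test of NT1 against TBV. The 164 became 1083 with NT1p14 with TBVp13 turned and 1972 with NT1p12 with TBVp12 turned. On 13 arrays they were 806 with the block, 958 without, 1921 with the ribosomal and 2160 with the proteasome covariate. Leaving out a pair or an array gave 50 to 888 (50 without NT1 1 with TBV2, 574 without NT1p14 with TBVp13, 888 without NT1p12 with TBVp12, 97 and 327 without arrays 3 and 4 of NT1p12 with TBVp12).

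The count of lists went from 0 to 4 with NT1p14 with TBVp13 turned, to 1 with ribosomal centring, and to 2 on 13 arrays with the block, as independent arrays, or with the ribosomal covariate; it was 0 with an estimated correlation. Leaving out a pair gave 0 to 4: without NT1p14 with TBVp13 the pluripotency (-0.24), fibroblast (-0.20) and proteasome (-0.13) lists passed as lower and the stress list (0.09) as higher, and without NT1p12 with TBVp12 the cell cycle (0.26) and ribosomal (0.33) lists passed as higher. The block fit ran camera on pre-ranked statistics, since camera itself takes no block. Among the named genes Acy3 (-0.21) and Brk1 (-0.15) reversed with NT1 in Cy5 only, and the cause was not tested. Mdh1b (-0.14) and Ccdc74a (-0.0090) reversed with NT1p14 with TBVp13 turned. That follows by arithmetic, as their value in this pair was larger than those of the other pairs together. The table holds no signal over background, so dim probes could not be set apart.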

Other observations

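The fit with the ribosomal covariate, the sign patterns, and the tests of fibroblast content, rounding and chance were chosen after the results were seen.

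Beyond the genes named by the rule, several list members had the same sign in all 3 independent pairs without passing the threshold. The imprinted transporter gene Slc38a4 was at -0.60, and the imprinted genes Peg3 and H19 were at 0.31 and 0.34. The stress response gene Gclm was at 0.42 and the glycolysis regulator Pdk1 at 0.44. A single pair weighed heavily for Pdk1, at 0.80 in NT1p14 with TBVp13 against 0.20 and 0.32 in the others. The same held for Slc38a4, at -1 in NT1p12 with TBVp12 against -0.50 and -0.29. With all 13 arrays taken as independent and a dye term, 10 probes passed in limma, 1 higher and 9 lower, among them Fgf4 at -0.53, Rims1 at -0.38 and Fubp1 at -0.47. With the ribosomal covariate 98 probes passed, 45 higher and 53 lower, the 10 included, among them Pou5f1 at -0.59, Zfp42 at -0.98 and, as higher, Dnmt3l at 0.79. These fits count repeats of the same RNA.

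A hypothesis is that pluripotency genes were lower in NT1, since 7 of 21 (33.3%) lay below 0 in all 3 pairs against 5.45% of all 7968 genes. Zfp42 (-0.01) and Esrrb (-0.02), however, were about 0 in NT1 1 with TBV2. Utf1 was at -0.06 in NT1p14 with TBVp13 and Zfp296 at -0.09 in NT1p12 with TBVp12. Pou5f1 was below 0 in NT1p14 with TBVp13 on array 3 alone, at -1 against 0. The list median was 0.08 without NT1p12 with TBVp12. The fibroblast median was -0.36 (SE over genes 0.10) in NT1 1 with TBV2 and -0.25 in NT1p12 with TBVp12, but 0.44 in NT1p14 with TBVp13. Fibroblast genes were thus not higher in NT1 in every pair. These medians cannot decide on fibroblast content. In NT1 1 with TBV2 the pluripotency median was itself about 0 (-0.01), and in NT1p12 with TBVp12 ribosomal, proteasome and cell cycle genes were lower too. Rounding is argued against for 5 of the 7 only, Klf4, Esrrb, Fgf4, Utf1 and Zfp296, which had decimals on all 11 arrays. Of the list genes with such decimals 5 of 11 lay below 0 in all 3 pairs, against 6.75% of 4533 genes. The exact one-sided hypergeometric p of 0.00045 takes genes as independent. The 5 also belong to the 7 that prompted the test, so this p does not bear on chance. The count holds for the directions as labelled, and turning any pair removes the 7 by construction. Turning NT1p14 with TBVp13 gave 4 other genes of 21 (against 16.2% of all genes). Turning NT1p12 with TBVp12 gave 0 (against 21.6%), and turning NT1 1 with TBV2 gave 1 (against 5.30%). Chance stays open: the exact hypergeometric p of 8.1e-05 takes genes as independent and the list was picked from 20, while camera with the correlation within the list estimated at 0.26 gave p = 0.44. Even if the pattern holds, it could come from the mutation or from any other difference between 1 NT1 and 1 TBV line, which the design does not separate.

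Turning the signs of the pairs gives 4 patterns, too few for a share under 0.05. The labelled signs gave 164 probes at an unadjusted p under 0.05 and 3 of the 4 patterns gave as many or more, the highest other being 1972, and all 4 patterns gave 0 past the threshold, the highest other being 0. A pattern with several times the real count points to a structure of the samples, here the opposite ratios of NT1p14 with TBVp13 and NT1p12 with TBVp12.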
